A study of Mus musculus with 16 samples.

How the data were processed

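The data were 16 arrays of an Affymetrix mouse platform, 1 array per sample, from RNA of sorted mouse lymphocytes. Per the labels' protocols, RNA was isolated with TRIZOL after sorting, amplified, and turned into biotinylated cRNA targets. The values deposited by the authors are intensities, 1 per probe set and array, and per the submitters' processing notes they were made with RMA, a method that corrects background, normalizes between arrays and summarises the probes of a set. Its version and settings, and which arrays were normalized together, are not given in the sources used here. The deposited intensities are on a linear scale, with array medians from 30.4 to 76.2. Medians were close within each pair of groups (51.3 in NKT and 51.8 in CD4T, 31 in CD8aaT and 31.2 in CD8abT, 72.6 in B1 and 75.1 in B2 over all values of a group) and far apart between pairs. Levels were therefore compared only within a pair, and pairs only through their differences, except that 1 test of the closing section sets gains on NKT arrays beside B2 levels. RMA compresses the fold changes of dim probe sets, and a level alone does not show whether a gene was expressed. Scanner files were not used here.

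The file holds 12488 probe sets. The 66 control probe sets were left out of the tests, leaving 12422. Gene names came from the platform annotation, with 10833 probe sets paired with 1 gene symbol, 396 with several and 1193 not listed. The 10833 named 8251 genes, 10817 of them were matched by Entrez number to a RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. No gene was named from a probe set with several symbols, except that the shared probe set of Klrb1b and Klrb1c was read as a label check. Genome coordinates were not used here. Different probe sets of a gene were tested separately.

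Groups and replicate numbers came from the sample titles. Differences were fitted on log2 of the deposited intensities with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with 6 group means over all 16 arrays, so that all groups share 1 estimate of the spread per probe set. Contrasts were the innate-like minus the adaptive group of each pair, their average, the differences between pairs and the F test over the 3 pairs. p-values were adjusted by Benjamini-Hochberg over 12422 probe sets per contrast and called under 0.05. The series describes its replicates as biological, without saying whether they came from separate animals or sorts, so p-values measure the spread between these samples. A count shared by 3 pairs was set beside that for independent lists and beside the count with 1 pair turned. No filter on dim probe sets was applied.

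The replicate numbers were taken to pair the samples in the T cell groups, by a check made before the calls of the fits were compared. Deviations from the group means correlated between same-numbered arrays at 0.76, 0.65 and 0.67 in NKT and CD4T and at 0.64, 0.60 and 0.66 in CD8aaT and CD8abT, all above the minimum of 0.1. In B1 and B2 the value was 0.69, where 2 arrays per group make both pairs' values equal, too few for the rule, so these numbers were not taken to pair the samples and blocked values stand beside results of the T cell pairs and of all 3 pairs together. The pairing comes from the data and not from a label. In NKT and CD4T, replicates 2 and 3 also correlated across numbers (0.57 and 0.67). The check there sets replicate 1 apart from the others and does not show that replicates 2 and 3 are paired by number. Replicate 1 of NKT and CD4T deviated together with replicate 1 of B1 and B2 as well (0.57 to 0.73), while replicate 1 of CD8aaT and CD8abT did not (-0.17 to -0.01). No array's values were a copy of another's in its group, since at most 1 probe set had an equal value on both. This check cannot tell repeated arrays of 1 RNA from separate samples. The SD of the log2 difference between replicates 2 and 3 was 0.162 in CD4T and 0.126 in NKT, against 0.383 to 0.634 for pairs with replicate 1 in these groups. Whether replicates 2 and 3 are independent there is not known, and if they are not, the p-values are too small. All were kept as separate replicates.

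The 27 gene lists, among them NK-cell receptors and adaptors, interferon-induced genes and macrophage markers, were fixed from textbook knowledge before the data were examined, as were the tests, the groups and the rule for named genes. Each list was tested in each pair (81 tests, adjusted together) with limma's fry on the brightest probe set of each gene. It asks whether members move one way on balance and does not compare the list with other genes. Some genes are on more than 1 list, and markers of other cell types can be expressed by the sorted cells as well. Of the 21 calls, 11 held with camera and an estimated correlation. The rule named, per pair, up to 10 genes with the largest increase and 10 with the largest decrease among called probe sets with 1 proper gene symbol and no overlap between replicates, genes of the sort gates being given as label checks instead, up to 10 and 10 genes shared by all pairs, up to 4 members per list with the smallest p, and list members called in opposite directions. In the 3 pairs it took 20, 11 and 20 genes as the largest changes.

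The steps were tested on simulated data with the real means and residual spreads of 12422 probe sets and 200 changed ones. Of 100 probe sets changed by 1 on the log2 scale 83%, 79% and 63% were called in the NKT, CD8 and B cell comparisons, and of 100 changed by 2 it was 94%, 95% and 91%, with 8, 11 and 11 unchanged probe sets called. A list shifted by 1 was called in 20 of 20 draws in each comparison, and of 520 unshifted lists 2, 1 and 0 were called. The simulated arrays vary independently, so this holds no shared deviation of same-numbered arrays.

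Alternatives were quantile normalization over all arrays, median centring, an offset of 32 before log2, removal of the dimmest 40% of probe sets, eBayes with trend and robust settings, the replicate block, leaving out each array in turn, averaging the probe sets of a gene, a minimum log2 difference of 1, fits on the arrays of a pair alone, and camera with a preset correlation of 0.01 or an estimated one. Leaving out replicate 1 of every group and the beta-actin ratio as a covariate were added after seeing the data.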

Results

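Gene expression was measured on 16 single-colour oligonucleotide arrays in 6 sorted mouse lymphocyte populations that form 3 pairs, each with an innate-like and an adaptive member. Splenic NKT cells (CD3+CD4+NK1.1+, n = 3) were paired with splenic CD4 T cells lacking NK1.1 (CD4T, n = 3). CD8αα T cells (CD8aaT, n = 3) and CD8αβ T cells (CD8abT, n = 3) both came from RTOC, a culture that the labels give by this abbreviation, and differed in the dose of the agonist Smcy, 10 mM and 100 nM respectively as the labels write them. Whether the unit of the higher dose is a slip in the labels is not known, so the size of the gap between the doses is uncertain. Peritoneal B1 cells (n = 2) were paired with splenic B2 cells (n = 2). About 100000 cells were sorted per spleen or peritoneal sample and about 50000 per RTOC sample. The series title sets innate against adaptive lymphocytes, and the question taken from it was which transcripts separate the members of each pair and which do so in all 3. All differences below are innate-like minus adaptive, on the log2 scale of the deposited intensities, with the SE of the fit, and p-values are limma's adjusted by Benjamini-Hochberg over 12422 probe sets. The number of arrays limits the precision.

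The genes of the sort gates were read first, as a check on the labels. In NKT cells a probe set shared by Klrb1b and Klrb1c, the latter encoding NK1.1, lay 3.67 ± 0.15 higher (12.7-fold, adjusted p = 5e-09), and Cd3e did not pass the test (-0.03 ± 0.22). Cd4 was -0.64 ± 0.17 in NKT cells (adjusted p = 0.11, and 0.0095 with the replicate number as a block). Cd8b1, the chain absent from the CD8αα gate, was 45.5-fold lower in CD8aaT cells (-5.51 ± 0.34, adjusted p = 3.6e-06), and Cd8a was -0.80 ± 0.14 (adjusted p = 0.03). Ighd was lower in B1 cells (-1.25 ± 0.18, adjusted p = 0.0017), IgD being part of the gate. Itgam, which encodes CD11b, was dim in both B cell groups (mean log2 5.37 in B1 and 5.36 in B2) and did not separate them. The brightest pair of Ighm probe sets were each 0.54 on the log2 scale above B2 cells in B1 cells, without passing the test (adjusted p = 1 for both).

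In NKT cells transcripts of Il4 and Ifng, of cytotoxic effectors and of NK-cell receptors were higher than in CD4 T cells, and those of naive T cell homing were lower. Il4 was 14.3-fold higher (3.84 ± 0.26, n = 3 against 3, adjusted p = 7.9e-07) and Ifng 6.16-fold (2.62 ± 0.20). Zbtb16, which encodes the transcription factor PLZF that NKT cells need to develop, was 9.37-fold higher (3.23 ± 0.26, adjusted p = 5.8e-06). This holds for a dim probe set, while a brighter one of the gene was not called. Fasl, the ligand of the death receptor Fas, was 7.49-fold higher and the chemokine Ccl5 8.59-fold. The T cell receptor gamma segments Trgv1 and Trgv4 were each 15.5-fold higher (3.95 ± 0.15 and 3.95 ± 0.20), values that are uncertain because variable segments share sequence.

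The other genes with the largest increases in NKT cells were the matrix metalloproteinase Mmp9 (3.66 ± 0.17), the surface receptor Cd160 (3.26 ± 0.29), the fibrinogen-like gene Fgl2 (3.25 ± 0.20 on its brighter probe set, while a dim probe set of the gene was not called) and the annexin Anxa1 (2.73 ± 0.24). The largest decreases were those of the actin cross-linker Actn1 (10.2-fold, -3.35 ± 0.29), Tdrp (-2.84 ± 0.48), the interleukin 6 receptor chain Il6ra (-2.54 ± 0.36), Itm2a (-2.50 ± 0.36) and Nsg2 (-2.38 ± 0.22). Ccr7, the receptor that guides naive lymphocytes into lymph nodes, was 4.27-fold lower (-2.09 ± 0.24), and Cnn3, Trim59, the cytokine-signalling inhibitor Socs3 and Itga6 lay between -2.06 and -1.78. Trim59 passed only narrowly (adjusted p = 0.04), and 19 of these 20 genes stayed called without each array in turn, Trim59 being the exception. In all, 202 of 12422 probe sets were called, 135 higher and 67 lower in NKT cells. With the replicate number as a block 601 were called, 387 higher and 214 lower, all 202 among them. Replicate 1 of both groups stood apart from replicates 2 and 3, with an 18S ribosomal control intensity of 1326 (CD4T) and 675 (NKT) against 52.7 to 59.2 on the other arrays of the pair. Without replicate 1 of every group, an alternative chosen after seeing this, 356 probe sets were called. In this pair that fit rests on replicates 2 and 3, which were closely alike within each group and may not be independent. The ratio of the 3' to the 5' Gapdh control was lower in NKT than in CD4T arrays of each number (6.15, 5.11 and 5.69 against 8.48, 5.85 and 5.83). Without NKT replicate 2 the count was 134, as it was with a minimum difference of 1. Without CD4T replicate 1 it was 242, 128 higher and 114 lower.

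**Figure D1:**
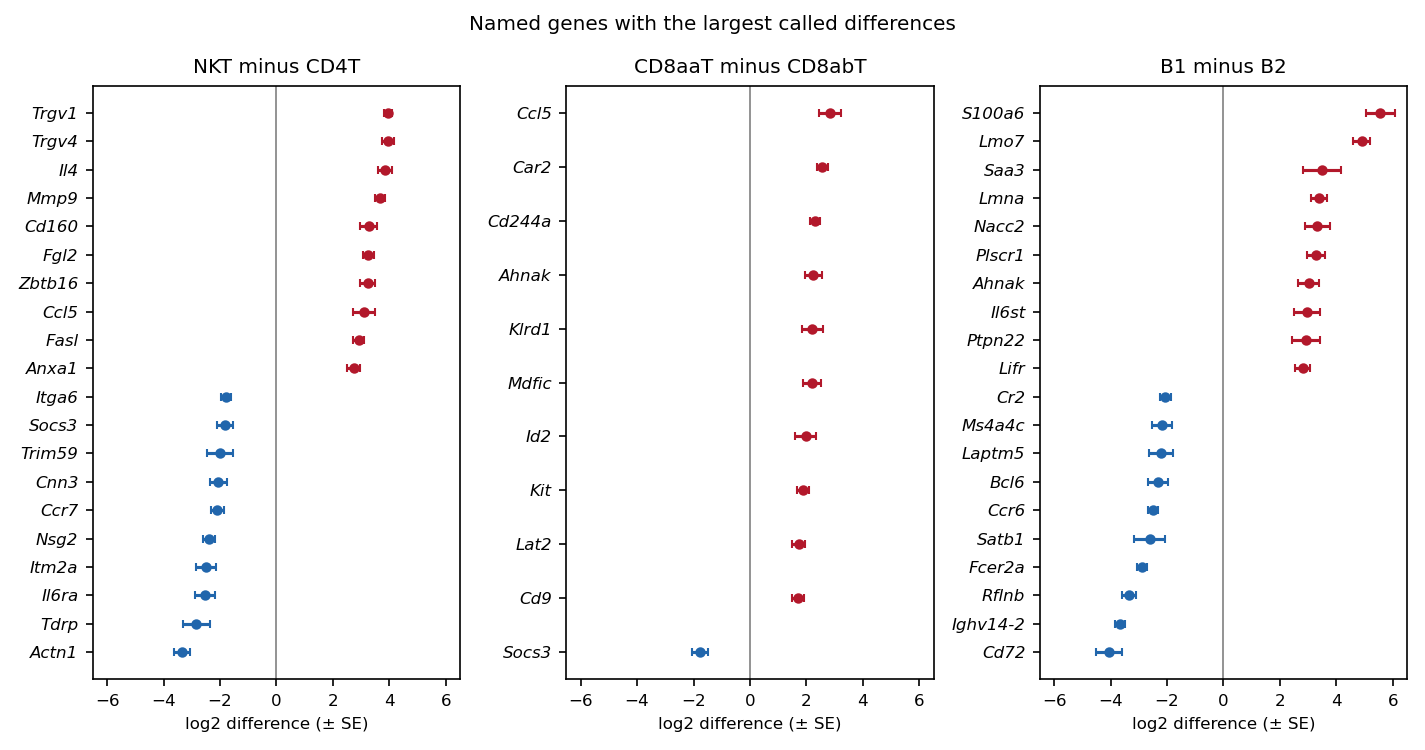
Log2 difference (x axis, points, with the SE as bars) of the named genes with the largest called differences, genes of the sort gates left aside, innate-like minus adaptive, in NKT against CD4T cells (3 arrays each), CD8aaT against CD8abT cells (3 each) and B1 against B2 cells (2 each). The values run from -3.35 for Actn1 to 3.95 for Trgv1 and Trgv4 in the NKT pair, from -1.77 for Socs3 to 2.84 for Ccl5 in the CD8 pair, and from -4.05 for Cd72 to 5.55 for S100a6 in the B cell pair.

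Of the 27 gene lists fixed before the data were examined, 12 were called in the NKT comparison by limma's fry test, which asks whether the members move one way on balance. Among NK-cell receptors and adaptors 4 of 11 measured members rose (6 adjusted over the list alone): Klrd1 (2.69 ± 0.37), Klra3 (2.24 ± 0.14), the activating receptor Klrk1 (2.18 ± 0.15) and the signalling adaptor Tyrobp (1.76 ± 0.36), with an adjusted p for the list of 1.9e-06. Among cytotoxic effectors 3 of 9 rose (6 over the list alone), namely Fasl, the protease Ctsw (2.62 ± 0.25) and, narrowly, perforin, Prf1 (0.58 ± 0.14, adjusted p = 0.049), with an adjusted p for the list of 1.2e-06. Effector and innate-lineage transcription factors had 4 of 12 higher (5 over the list alone, list adjusted p = 2.2e-05): Id2 (2.60 ± 0.36), Bhlhe40 (2.26 ± 0.29), Rora (1.65 ± 0.20) and Prdm1 (0.94 ± 0.21). This list used the brighter probe set of Zbtb16, which was not called. Of 7 inflammatory chemokine receptors Ccr2 (2.64 ± 0.21), Cxcr3 (2.56 ± 0.34) and Ccr9 (1.70 ± 0.24) rose (3 over the list alone, list adjusted p = 2.6e-05). Of 7 naive and lymph-node homing genes 4 fell (5 over the list alone, list adjusted p = 2.6e-05), namely Ccr7, the transcription factors Klf2 (-1.54 ± 0.25) and Lef1 (-0.62 ± 0.13) and the egress receptor S1pr1 (-1.36 ± 0.13).

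The remaining calls in the NKT comparison rested on fewer members or were lost in part. Il4 and Ifng were the cytokines that rose (2 of 11, 3 over the list alone, list adjusted p = 0.0027), and the list's adjusted p was 0.21 with an estimated correlation. Of 10 antibody secretion genes Jchain (0.77 ± 0.13) and Prdm1, which also acts in effector T cells, rose (6 over the list alone, list adjusted p = 0.0015). Of 21 adhesion, migration and memory-associated genes Anxa1, Icam1 (2.32 ± 0.23) and the integrin Itgal (0.71 ± 0.16) rose while Cd9 (-1.23 ± 0.21) and Crip1 (-1.17 ± 0.27) fell (7 and 3 over the list alone, list adjusted p = 0.015). That list had an adjusted p = 0.092 with an estimated correlation. Cytokine receptors were called higher (list adjusted p = 0.023, 2 of 15 higher, Il12rb1 at 1.37 ± 0.18 and Il18rap at 1.29 ± 0.17, and 1 lower, Il6ra, with 2 and 1 over the list alone). Their list had an adjusted p = 0.13 with an estimated correlation and 0.076 with the replicate block. Inhibitory receptors and SOCS genes had Cd160, Socs2 (2.61 ± 0.29) and Cish (0.58 ± 0.13) higher and Socs3 lower among 11 (3 and 3 over the list alone, list adjusted p = 0.043), with an adjusted p = 0.55 with an estimated correlation and 0.94 with the block. B1 cell markers were called lower on Cd9 alone of 7 (2 over the list alone, list adjusted p = 0.0098, and adjusted p = 0.092 with an estimated correlation). Follicular B cell markers were called lower on Klf2 and Ccr7, which T cells also use (2 of 7, 3 over the list alone, list adjusted p = 0.014, and adjusted p = 0.12 with an estimated correlation).

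Markers of other cells moved in part with the NKT group. Of 15 pan-B cell markers the MHC class II genes H2-Aa (1.42 ± 0.28) and H2-Ab1 (1.17 ± 0.27, adjusted p = 0.044) and the co-receptor Cd72 (1.90 ± 0.38) were higher (3 over the list alone), while the adjusted p of the list was 0.13, and 0.00084 with the block. Of 14 macrophage markers Lyz2 (2.08 ± 0.35) and Csf1r (0.60 ± 0.13, adjusted p = 0.039) were higher (2 over the list alone), with an adjusted p for the list of 0.15, and 0.01 with the block. The call of H2-Ab1 was lost in 19 of 27 alternatives and that of Csf1r in 13, and a dim other probe set of Csf1r did not rise. Of 10 chemokines 1 rose, Ccl5 (2 over the list alone, list adjusted p = 0.082), and of 9 double-positive thymocyte genes 1 fell, Dntt (-0.71 ± 0.17, adjusted p = 0.049, 2 over the list alone, list adjusted p = 0.082). No member was called in the other lists, alone or over all probe sets. Their adjusted p was 0.54 for interferon-induced genes, 0.94 for antigen-receptor immediate-early genes, 0.97 for cell cycle genes, 0.75 for apoptosis regulators, 0.8 for Toll-like receptors, 0.92 for pan-T cell markers, 0.44 for granulocyte and mast cell markers, 0.63 for erythroid and platelet markers, 0.6 for stroma and fibroblast markers, 0.32 for heat shock genes (0.0065 with the block) and 0.56 for glycolysis genes. With the block Mx1, Zap70, Ddit3 and Tpi1 were called higher in these lists and Cd247, 1 interferon-induced gene and 1 immediate-early gene lower. In the lists given before them the block called 6 NK-cell receptors, 4 cytotoxic effectors (Gzma added), 3 cytokines (Csf2 added), 2 chemokines (Xcl1 added), 5 transcription factors, 6 antibody secretion genes (Xbp1 and Sec61b among those added) and 6 adhesion-associated genes higher. Lower with the block were 3 adhesion-associated genes, 5 naive and homing genes, 3 inhibitory receptors and SOCS genes and 3 B1 cell markers (Cd5 and Ctla4 added to both), 3 follicular markers (Cd55 added) and 2 thymocyte genes (the gate gene Cd4 added). Medians of the cytokines and of the chemokine receptors were both -0.05, opposite in sign to their means (0.61 and 0.92) and tests. The cell cycle and Toll-like receptor lists likewise had a median of -0.02 and a mean of 0.01.

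CD8aaT cells had higher transcripts of NK-cell receptors, of the chemokine Ccl5 and of adhesion-associated genes than CD8abT cells, with few genes lower. Ccl5 was 7.14-fold higher (2.84 ± 0.40, n = 3 against 3, adjusted p = 0.0088). Carbonic anhydrase 2, Car2, was 5.90-fold higher (2.56 ± 0.19, adjusted p = 2.2e-05), and the receptor Cd244a, known as 2B4 on NK cells, 4.91-fold (2.30 ± 0.18, adjusted p = 2.3e-05). The scaffold gene Ahnak was 4.71-fold higher (2.24 ± 0.30, adjusted p = 0.0055) and the stem cell factor receptor Kit 3.66-fold (1.87 ± 0.21, adjusted p = 0.0012). Socs3 was 3.41-fold lower (-1.77 ± 0.28, adjusted p = 0.023).

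The other named increases in CD8aaT cells were Klrd1, which encodes CD94 (2.20 ± 0.37, adjusted p = 0.031), Mdfic (2.19 ± 0.32), Id2 (1.97 ± 0.36, adjusted p = 0.049), the adaptor Lat2 (1.72 ± 0.22) and the tetraspanin Cd9 (1.71 ± 0.21). Of these 11 genes 6 stayed called without each array in turn. Ccl5 and Mdfic lost their calls without CD8aaT replicate 2, Klrd1 when any 1 of 9 arrays was left out, Id2 with any 1 of 14 and Socs3 with any 1 of 4. The call of Id2 was lost in 20 of 27 alternatives. The count was 23 probe sets, 19 higher and 4 lower, and with the replicate block it was 398, 325 higher and 73 lower, the 23 among them. The 4 lower ones included the gate genes Cd8b1 and Cd8a. Agonist dose and lineage are the same factor in this design. The ratio of the 3' to the 5' beta-actin control, a sign of RNA or target length, also differed without overlap between the groups, at 6.57, 11.6 and 7.92 in CD8abT and 5.8, 5.76 and 5.15 in CD8aaT arrays. With it as a covariate, chosen after seeing this, 11 probe sets were called, 10 of them among the 23. The 18S control intensity (129, 857 and 716 in CD8abT, 66.5, 273 and 249 in CD8aaT) and the Gapdh ratio (24, 30.4 and 9.47, against 20.9, 17.6 and 7.37) were also lower in the CD8aaT array of each number. With 1 array left out the count lay between 10 (without CD8aaT replicate 2) and 57 (without CD4T replicate 1). It was 2 with the arrays of the 2 groups alone, 9 with an offset of 32 and 190 without replicate 1 of every group.

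By list, 2 of 11 NK-cell receptors rose in CD8aaT cells, Cd244a and Klrd1 (4 over the list alone, list adjusted p = 0.00013). Of 21 adhesion, migration and memory-associated genes Ahnak, Cd9 and the annexin Anxa2 (1.64 ± 0.21) rose (6 over the list alone, list adjusted p = 0.0035). Cytotoxic effectors were called higher as a list (adjusted p = 0.023) with no member called over all probe sets and 1 of 9 over the list alone. Srgn was 0.86 ± 0.23 and Ctsw 0.65 ± 0.25, both called with the block, as was Fasl, and the list had an adjusted p = 0.07 with an estimated correlation. Double-positive thymocyte genes were called lower as a list (adjusted p = 0.017), all 9 measured members lying below 0 and none called, with Sox4 at -0.75 ± 0.26 and Cd24a at -0.66 ± 0.30, and the list had an adjusted p = 0.07 with an estimated correlation. B1 cell markers were called higher on Cd9 (1 of 7, 2 over the list alone, list adjusted p = 0.019), with a median of -0.00 against a mean of 0.27, an adjusted p = 0.23 with an estimated correlation and 0.38 with the block. With the block Tyrobp, Klrb1a, S100a10 and Plscr1 were also called higher in these lists and Cd5 lower. The beta-actin and Gapdh ratios and the 18S signal given above differed between the same groups.

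All 14 interferon-induced genes measured lay above 0 in CD8aaT cells, with a median of 0.77, and none was called over all probe sets (1 over the list alone). The adjusted p of the list was 0.16, and 0.025 with the replicate block, where 8 members were called. Rsad2 was 1.14 ± 0.26, Mx1 1.05 ± 0.42 and Gbp3 0.97 ± 0.34. All 11 pan-T cell markers lay below 0 (median -0.28, none called, 3 over the list alone), with Cd2 at -1.22 ± 0.24 and Thy1 at -0.91 ± 0.31, both called with the block, as was Cd6, and an adjusted p for the list of 0.085, or 0.0065 with the block. Among effector and innate-lineage transcription factors 1 of 12 rose, Id2 (2 over the list alone, list adjusted p = 0.059, and 0.036 with the block, which also called Gata3 higher). Among apoptosis regulators 1 of 10 rose, Bcl2l11, which encodes the death-promoting protein Bim (1.24 ± 0.20, 1 over the list alone, list adjusted p = 0.44). Its call was lost in 11 of 27 alternatives, and its 2 other probe sets, both dim, did not rise.

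Chemokines had Ccl5 higher in CD8aaT cells (1 over the list alone, list adjusted p = 0.13) and inhibitory receptors had Socs3 lower (1 higher and 1 lower over the list alone, list adjusted p = 0.93). No member was called over all probe sets in the remaining lists. With the replicate block Cxcr3, Il7r, Ifngr1, Mcm4, Hspa5 and Dnajb1 were called higher in these and Satb1, Ccr7 and Lyz2 lower, and among inhibitory receptors Cd160 was called higher and Cd5 lower. Their adjusted p was 0.8 for cytokines, 0.84 for inflammatory chemokine receptors (1 higher over the list alone), 0.84 for naive and homing genes (1 higher and 1 lower over the list alone), 0.4 for cytokine receptors (1 higher over the list alone), 0.49 for immediate-early genes, 0.93 for cell cycle genes, 0.92 for Toll-like receptors, 0.93 for pan-B cell markers, 0.6 for follicular B cell markers (1 lower over the list alone) and 0.24 for antibody secretion genes. It was 0.39 for macrophage markers (0.04 with the block), 0.31 for granulocyte and mast cell markers, 0.14 for erythroid and platelet markers, 0.41 for stroma and fibroblast markers, 0.84 for heat shock genes and 0.53 for glycolysis genes. Median and mean had opposite signs for inflammatory chemokine receptors (-0.10 and 0.10), immediate-early genes (-0.00 and 0.13), cell cycle genes (-0.02 and 0.01), inhibitory receptors (0.01 and -0.05) and follicular B cell markers (0.03 and -0.15).

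**Figure D2:**
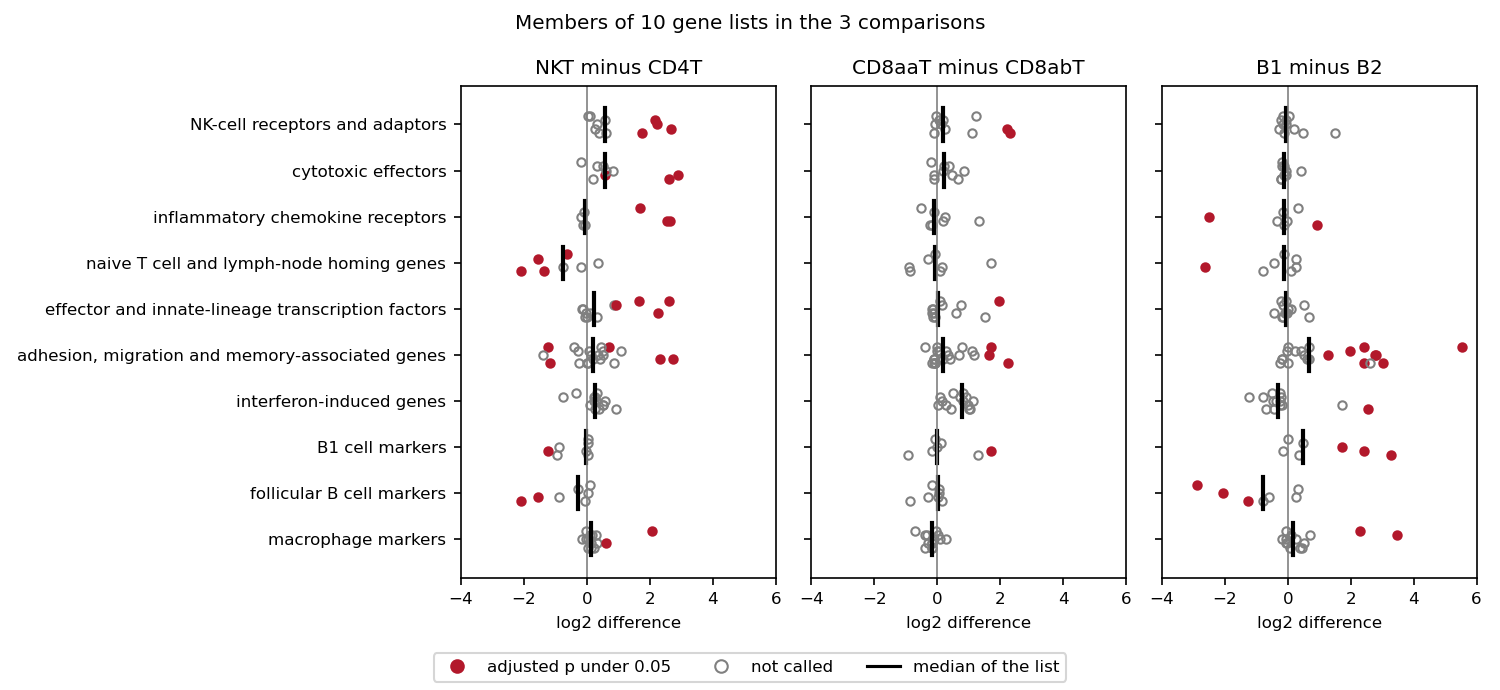
Log2 difference (x axis, 1 point per gene) of the measured members of 10 gene lists in the 3 comparisons, filled where the gene was called, with the median of the list as a black bar. In the NKT panel 4 naive and homing genes are called lower and 4 NK-cell receptors higher, in the CD8 panel all 14 interferon-induced genes lie above 0 with none called, and in the B cell panel 8 adhesion-associated genes are called higher.

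In peritoneal B1 cells adhesion, migration and memory-associated genes were higher as a list than in splenic B2 cells, and follicular B cell markers were lower. S100a6 was 46.9-fold higher (5.55 ± 0.51, n = 2 against 2, adjusted p = 2.9e-05) and Lmo7, an actin-associated LIM domain gene, 29.8-fold (4.90 ± 0.30, adjusted p = 7.3e-07). The phospholipid scramblase Plscr1 was 9.62-fold higher (3.27 ± 0.31) and the receptor chains Il6st, which encodes gp130, and Lifr were 7.86-fold and 6.94-fold higher. Cd72 was 16.5-fold lower (-4.05 ± 0.46, adjusted p = 0.00024), and Fcer2a, which encodes the follicular marker CD23, 7.34-fold lower (-2.88 ± 0.18, adjusted p = 7.3e-07).

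The other named increases in B1 cells were the acute-phase gene Saa3 (3.48 ± 0.68), lamin A/C, Lmna (3.38 ± 0.29), Nacc2 (3.32 ± 0.44), Ahnak (3.02 ± 0.37) and the phosphatase Ptpn22 (2.93 ± 0.50). Of the 5 probe sets of Lifr 1 was called. The other named decreases were Rflnb (-3.35 ± 0.25), the chromatin organiser Satb1 (-2.62 ± 0.55), the chemokine receptor Ccr6 (-2.51 ± 0.18), the germinal centre transcription factor Bcl6 (-2.33 ± 0.35), Laptm5 (-2.21 ± 0.43), Ms4a4c (-2.19 ± 0.35) and the complement receptor Cr2 (-2.06 ± 0.19). The heavy chain segment Ighv14-2 was -3.67 ± 0.17, a value that is uncertain because variable segments share sequence. Of these 20 genes 13 stayed called without each array in turn. Saa3, Il6st, Ptpn22, Satb1, Bcl6, Laptm5 and Ms4a4c each lost the call without at least 1 of the B cell arrays. The count was 142 probe sets, 98 higher and 44 lower. Without B2 replicate 1, B2 replicate 2 or B1 replicate 2 it was 82, 64 and 77, and with the B cell arrays alone 50. With an offset of 32 it was 214. Leaving out replicate 1 of every group leaves 1 array in each B cell group, so no B cell count is given for that fit. The 18S control intensity was lower in the B1 than in the B2 array of each number (776 and 33.4 against 877 and 62.6). Tissue and lineage are the same factor in this design, since B1 cells came from the peritoneum and B2 cells from the spleen.

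By list, 8 of 21 adhesion, migration and memory-associated genes rose in B1 cells (9 over the list alone, list adjusted p = 1.1e-05). Beside S100a6 these included the integrin Itgb1 (2.79 ± 0.26), Anxa2 (2.78 ± 0.26) and Cd9 (2.43 ± 0.26). Of 7 B1 cell markers Plscr1, Cd9 and Ctla4 (1.71 ± 0.37) rose (3 over the list alone, list adjusted p = 8.5e-06). Of 7 follicular B cell markers Fcer2a, Cr2 and the gate gene Ighd fell (4 over the list alone, list adjusted p = 7.7e-05). Inflammatory chemokine receptors were called lower as a list (adjusted p = 0.021), with Ccr6 lower and Ccr1 higher (0.94 ± 0.17) of 7 and the same counts over the list alone, and the list had an adjusted p = 0.68 with an estimated correlation.

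Members were called in lists that did not pass the test as well. Of 14 macrophage markers Saa3 and Lyz2 (2.29 ± 0.43 on its brighter probe set, while a dim one did not rise) were higher in B1 cells (2 over the list alone), with an adjusted p for the list of 0.13, while the other 12 had a median of 0.08 and none was called. These markers stand beside all B1 increases given above. Of 15 pan-B cell markers Cd72 and Cd22 (-0.87 ± 0.17) were lower (2 over the list alone, list adjusted p = 0.085). Of 12 immediate-early genes Myc (1.70 ± 0.27) was higher and Dusp2 (-1.71 ± 0.33) lower, with the same counts over the list alone (list adjusted p = 0.66). Gbp2 was the interferon-induced gene that rose (2.55 ± 0.30, 1 of 14, 2 over the list alone, list adjusted p = 0.93), Cxcl13 the chemokine (1.18 ± 0.24, 1 of 10, 1 over the list alone, list adjusted p = 0.86), Ctla4 the inhibitory receptor (1 of 11, 1 over the list alone, list adjusted p = 0.055), Epcam the stroma and epithelial marker (1.17 ± 0.15, 1 of 15, 1 over the list alone, list adjusted p = 0.73) and Satb1 the naive and homing gene that fell (1 of 7, 1 over the list alone, list adjusted p = 0.24).

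The remaining lists had no member called over all probe sets in B1 cells. The adjusted p of the list was 0.86 for NK-cell receptors, 0.37 for cytotoxic effectors, 0.44 for cytokines (1 lower over the list alone), 0.75 for effector transcription factors, 0.53 for cytokine receptors, 0.44 for cell cycle genes, 0.49 for apoptosis regulators, 0.44 for Toll-like receptors, 0.27 for double-positive thymocyte genes, 0.93 for pan-T cell markers (1 higher over the list alone), 0.4 for antibody secretion genes (1 higher over the list alone), 0.5 for granulocyte and mast cell markers, 0.6 for erythroid and platelet markers, 0.84 for heat shock genes and 0.46 for glycolysis genes. Median and mean had opposite signs for NK-cell receptors (-0.07 and 0.10), chemokines (-0.11 and 0.03) and stroma markers (-0.05 and 0.07).

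Across the 3 pairs 1 probe set was called in the same direction each time, which the annotation pairs with no gene, at -2.31 ± 0.13 in NKT, -0.88 ± 0.13 in CD8aaT and -0.91 ± 0.16 in B1 cells. It was no longer called in all 3 when any 1 of 7 of the 16 arrays was left out, with an offset of 32, with the beta-actin covariate or with a minimum difference of 1. When the direction of the NKT, CD8 or B cell pair was turned, this fit called 1, 0 and 0. The count of 1 thus did not exceed that with the NKT pair turned. With the replicate block 14 were called in all 3 pairs, 12 higher and 2 lower, against 0.17 and 0.014 for independent lists and against 1, 4 and 3 when the direction of the NKT, CD8 or B cell pair was turned. The lists share 1 estimate of the spread per probe set, so they are not independent. With the CD8 pair turned 1 was higher and 3 lower, against 0.039 and 0.064 for independent lists. With the B cell pair turned it was 1 and 2, against 0.12 and 0.021. The named genes higher in all 3 in that fit were Tyrobp (3.40-fold, 2.15-fold and 2.82-fold in the NKT, CD8 and B cell pairs) and, as log2 differences in the same order, Lysmd2 (1.58, 1.07 and 1.86), Fgl2 (3.25, 1.06 and 2.74), Evi2a (1.31, 0.98 and 2.11), Ahnak (0.87, 2.24 and 3.02), Napsa (0.89, 0.61 and 0.58), S100a10 (0.51, 0.70 and 1.28), Plac8 (2.43, 0.50 and 1.64) and Itm2c (0.84, 0.47 and 0.93). Rflnb was the named gene lower in all 3 (-1.21, -0.80 and -3.35). These calls depend on the block, which was applied to the B cell arrays too, although their numbers were not taken to pair the samples. Without it Lysmd2 and Napsa were called in none of the pairs, Tyrobp in the NKT pair alone and S100a10 in the B cell pair alone. Ahnak was not called in the NKT pair, and Fgl2, Evi2a, Plac8, Itm2c and Rflnb were not called in the CD8 pair.

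**Figure D3:**
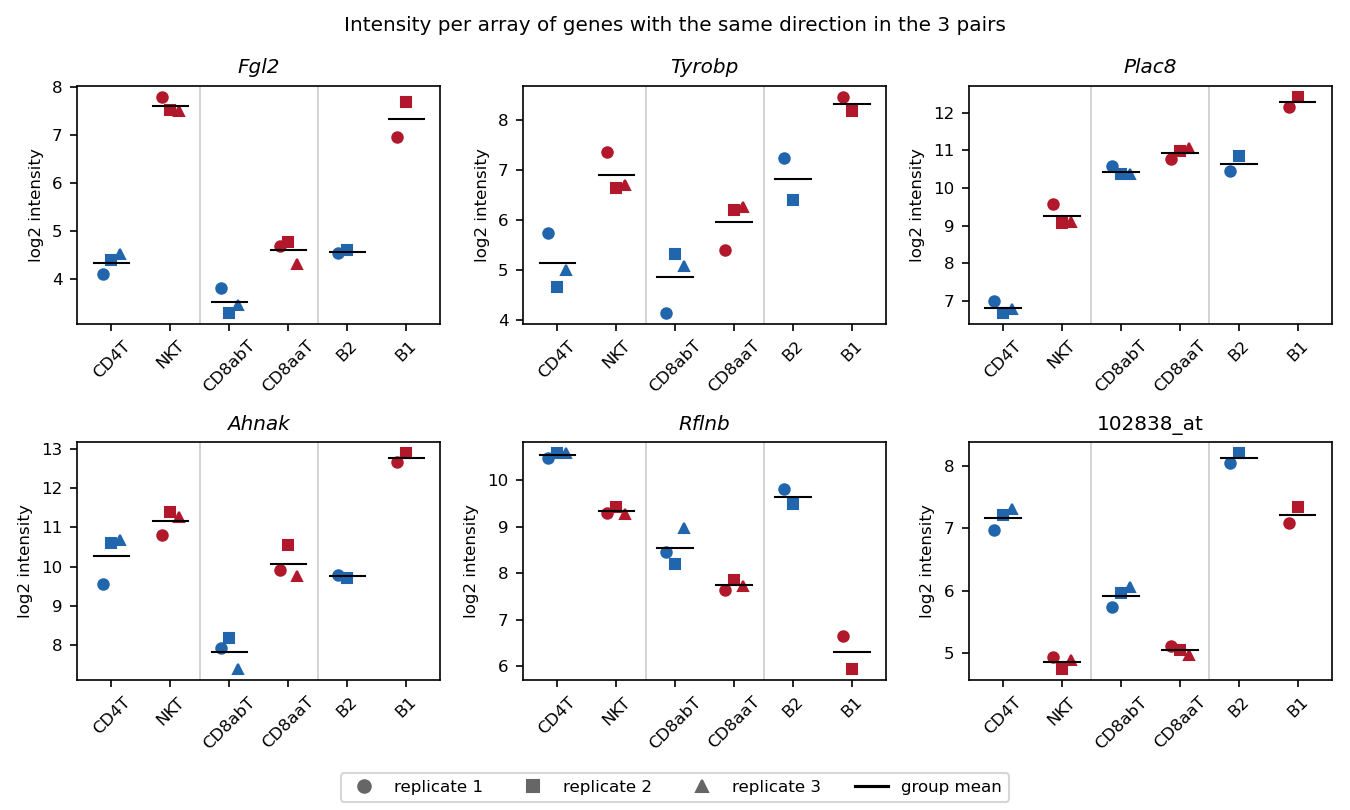
Log2 intensity (y axis) of 6 probe sets on each of the 16 arrays, by group, with replicate numbers as symbols, group means as bars, adaptive groups in blue and innate-like groups in red. Levels compare only within a pair, set off by the grey lines, and in each pair the mean of the red points of Fgl2, Tyrobp, Plac8 and Ahnak lies above that of the blue points and the mean of Rflnb and the unnamed probe set below it.

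Calls were also set side by side for each 2 of the comparisons. NKT and CD8aaT cells shared 5 probe sets higher and 2 lower with 1 opposite, against 0.21, 0.022 and 0.15 for independent lists. With the replicate block they shared 69 higher and 15 lower with 16 opposite, against 10, 1.3 and 7.9. In both T cell pairs the Gapdh 3' to 5' ratio was lower in the innate-like array of each number. The block does not remove such a difference, and its part in this overlap was not tested. NKT and B1 cells shared 7 higher and 4 lower with 6 opposite, against 1.1, 0.24 and 1. CD8aaT and B1 cells shared 3 higher and 1 lower with 1 opposite, against 0.15, 0.014 and 0.099. The lists share 1 estimate of the spread per probe set, so they are not independent, and opposite calls exceeded these values too. Across probe sets, which are not independent replicates, the log2 differences correlated at r = 0.24 (Spearman 0.17) between the NKT and CD8 pairs, 0.03 (0.03) between the NKT and B cell pairs and 0.21 (0.20) between the CD8 and B cell pairs. Without CD4T replicate 1 the r between the NKT and CD8 pairs was -0.12 and that between the NKT and B cell pairs -0.07. Between the CD8 and B cell pairs r was 0.02 without B1 replicate 2 and 0.07 without B2 replicate 1.

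The average of the 3 differences, each pair weighted equally, was led by Fgl2 (2.35 ± 0.12, adjusted p = 4.1e-07), S100a6 (2.26 ± 0.26), Ahnak (2.04 ± 0.19) and Ccl5 (1.84 ± 0.25) among genes named above that were higher, and by Rflnb (-1.79 ± 0.13, adjusted p = 2.9e-06), Ccr7 (-1.24 ± 0.15), Satb1 (-1.23 ± 0.28, adjusted p = 0.042) and Cnn3 (-1.23 ± 0.19) among those lower, leaving aside the gate gene Cd8b1. Of these, Fgl2, S100a6, Ahnak, Rflnb, Ccr7, Satb1 and Cnn3 had the same sign in each pair, while Ccl5 was -0.43 ± 0.49 in B1 cells. The B cell pair was the largest part for S100a6 (0.45, 0.79 and 5.55 in the NKT, CD8 and B cell pairs) and Satb1 (-0.19, -0.89 and -2.62). In all 200 probe sets were called, 149 higher and 51 lower, and 694 with the replicate block. The count was 61 with a minimum difference of 1. It was also lower without B2 replicate 1, B2 replicate 2 or B1 replicate 2, each of which leaves 1 array in a B cell group. Of the 200, 113 had the same sign in all 3 pairs and 114 differed between pairs by the F test, so the average often rested on part of the pairs.

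Some genes moved in opposite directions in different pairs. Cd9 was lower in NKT cells (-1.23 ± 0.21, adjusted p = 0.0051) and higher in CD8aaT (1.71 ± 0.21) and B1 cells (2.43 ± 0.26), and its F test of a difference between pairs gave an adjusted p of 2.9e-05. Crip1 was lower in NKT cells (-1.17 ± 0.27, adjusted p = 0.048) and higher in B1 cells (2.43 ± 0.33), and Cd72 was higher in NKT cells (1.90 ± 0.38) and lower in B1 cells (-4.05 ± 0.46). Over all probe sets 202 differed between pairs by the F test, with 86 between the NKT and CD8 pairs, 168 between the NKT and B cell pairs and 91 between the CD8 and B cell pairs. With the replicate block these counts were 716, 375, 573 and 275. With the dimmest 40% of probe sets removed 57 differed between the CD8 and B cell pairs.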

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

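The splits that part every replicate pair and the tests on MHC class II genes and macrophage markers were chosen after the result was seen.

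The innate-like minus adaptive difference was not alike in the 3 pairs. By limma's tests of the difference between pairs, 86 probe sets differed between the NKT and CD8 pairs, 168 between the NKT and B cell pairs and 91 between the CD8 and B cell pairs, and 202 by the F test over all 3. For the 86, 2 of 100 splits of the arrays within the pairs, the real split included, called as many, and the highest of the others called 93, but most of these splits mix the arrays of replicate pairs. Of the 32 splits that part every replicate pair of the T cells, as the real one does, 2 called as many, the other being the real one with the whole CD8 pair turned, which called 160. That split keeps every group together and adds the differences of the NKT and CD8 pairs in place of subtracting them, so it does not measure chance. Splits with the NKT pair as it is and part of the CD8 pair turned called 56 to 72, and these keep the real NKT difference. Those with part of the NKT pair turned called 0 to 4. The splits therefore do not decide whether chance could give this count.

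Cd9, lower in NKT cells and higher in CD8aaT and B1 cells, had an adjusted p of 2.9e-05 in the F test, Crip1 of 0.00098 and Cd72 of 0.00024. Genes with 1 direction in the 3 pairs differed in size: the F test gave 0.0014 for Fgl2, 0.001 for Rflnb and 0.0011 for Plac8. It gave 0.00096 for the unnamed probe set lower in all 3 pairs and 0.0011 and 0.00039 for a pair of unnamed probe sets that were higher in all 3 with the replicate block.

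MHC class II genes were higher in NKT than in CD4 T cells, H2-Ab1 narrowly, although the gate required CD3 and CD4. B cells in the NKT sort would bring all their abundant transcripts at a like share of the B2 level, if 1 scale factor between NKT and B2 arrays fits all genes. The median share gained by 10 other pan-B cell markers was 1.5%, 0.8% and 1% in the 3 replicates, against 8.5%, 4.1% and 4.6% for H2-Aa, H2-Ab1 and H2-Eb1, which argues against B cells as the whole cause. Cd72, which is among the 10, gained 15%, 26% and 26%, more than any of these. Cd74, also among them, gained -0.46%, 2.2% and 2.8%. In replicate 1 Cd79b gained 4.1% and Ms4a1 4.2%, against 0.66% and 0.045% in replicate 2 and 0.66% and 1.3% in replicate 3. The rest of the 10 lay between -0.61% (Spib) and 2.1% (Blk) in replicate 1. Some B cells in NKT replicate 1 therefore stay possible. Myeloid cells stay open (Lyz2 and, narrowly, Csf1r were higher, and the median difference of 12 other macrophage markers was 0.08, with -0.02, 0.09 and 0.19 in the replicates), as does expression by the NKT cells themselves, which was not tested.

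Many probe sets were higher in B1 cells, and macrophages of the peritoneum are a candidate source, since CD11b was part of the B1 gate, though IgM and IgD were as well. Lyz2 and Saa3 gained 2.88 and 2.06 times as much over B2 in replicate 1 as in replicate 2. Over the other 96 higher probe sets the upper quartile of this ratio was 0.97 and the median 0.798, so most did not share it. These 96 were picked by their calls on the same arrays, which favours like gains in both replicates. The reference is Lyz2 and Saa3 alone. The ratios therefore cannot settle whether macrophages are the cause for the set. For Lyz2 and Saa3 themselves macrophages stay open too, as the median difference of 12 other macrophage markers was 0.08, from -0.19 to 0.71, with 0 called by limma. Tissue and lineage cannot be told apart for any of these genes.

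Same-numbered arrays of a pair deviated together, with correlations from 0.60 to 0.76, and no label names what they share. With the beta-actin and Gapdh 3' to 5' ratios regressed out the correlations lay between -0.69 and 0.54, and with the 18S ribosomal signal regressed out between 0.09 and 0.66. Some stayed over 0.1 in each case and some did not. In NKT and CD4T they fell from 0.76, 0.65 and 0.67 to 0.18, 0.07 and 0.24 without the 3' bias. Without the 18S signal they fell to 0.14, 0.09 and 0.19 there. In CD8aaT and CD8abT they were 0.60, 0.66 and 0.59 without the 18S signal, against 0.64, 0.60 and 0.66 before. This argues against the 18S signal as the cause in the CD8 pair, if 1 slope per probe set fits all groups. Otherwise RNA 3' bias and ribosomal RNA in the target could each be part of the cause and stay open. No biological explanation was tested.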

How the results depend on the processing

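Leaving out replicate 1 of every group and the beta-actin ratio as a covariate were chosen after the data were seen. The cause of the changes given here was not tested, except that fewer arrays or probe sets enter some fits by construction.

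With the replicate number as a block, 601 (NKT), 398 (CD8), 353 (B cell), 694 (average) and 14 (shared by all pairs) probe sets were called in place of 202, 23, 142, 200 and 1. Between pairs the block gave 375 (NKT and CD8), 573 (NKT and B cell), 275 (CD8 and B cell) and 716 (F test). No probe set lost its call in the 3 pairs or the average. Among 81 list tests the block added 11 calls and ended 3. The NKT and B cell pairs shared 29 higher, 19 lower and 35 opposite with the block, against 6.6, 2.4 and 8.1 for independent lists. With it the CD8 and B cell pairs shared 27, 5 and 13, against 5.5, 0.83 and 5. In the B cell comparison the block added macrophage (adjusted p = 0.0098), pan-B (0.00084), naive and homing (0.035) and cytotoxic lists (0.048).

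Without replicate 1 of every group the counts were 356, 190, 227, 313 and 5. The beta-actin covariate gave 11 (CD8) and 0 (shared). An offset of 32 gave 9 (CD8), 214 (B cell) and 0 (shared), quantile normalization 2 shared, and trend and robust settings 2 shared. A minimum difference of 1 gave 134 (NKT), 61 (average) and 0 (shared). Fits on the arrays of a pair alone gave 2 (CD8) and 50 (B cell). Removing the dimmest 40% gave 57 between the CD8 and B cell pairs. Camera with an estimated correlation called 12 lists in place of 21, 11 of them shared.

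Leaving out 1 array at a time gave 134 to 242 (NKT), 10 to 57 (CD8), 64 to 164 (B cell), 127 to 218 (average) and 0 to 2 (shared). The NKT count was 134 without NKT replicate 2. The CD8 count was 57 without CD4T replicate 1, 14 without CD4T replicate 2, 13 without NKT replicate 3, 11 without CD8abT replicate 2, 10 without CD8aaT replicate 2 and 11 without CD8aaT replicate 3. The B cell count was 82, 64 and 77, and the average 131, 127 and 132, without B2 replicate 1, B2 replicate 2 and B1 replicate 2. The shared probe set lost its call without CD8abT replicate 2 or 3, CD8aaT replicate 2 or 3, or B2 replicate 1 or 2, and without B1 replicate 1, where another was called in its place. There were 2 without CD4T replicate 1, CD8abT replicate 1 or B1 replicate 2. A lone B cell array is assumed to vary like the other groups. Correlations between pairs ranged from -0.12 to 0.40, -0.07 to 0.09 and 0.02 to 0.31.

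Of 399 tests of named genes 116 were called, 60 of them under each of the 26 or 27 alternatives run for a gene, and 0 reversed. Dim probe sets have 26, as the filter removes them. Calls of Prf1, Lef1, Prdm1, Cish, Itgal, Dntt, Crip1 and Evi2a in NKT cells and of Ctla4 in B1 cells were lost in 11 to 20 of these. Of the 283 not called by limma, 78 were called under some alternative. Dim probe sets are limited by signal over background.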

Other observations

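The other splits of the arrays were planned before the counts were seen, and the splits that part every replicate pair, the tests on turned pairs with the replicate block and the choice of Trgv1 and Blk came after.

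Trgv1 had an intensity from 1155 to 1352 on the NKT arrays against 72.5 to 87.5 on the CD4T arrays, and from 2895 to 3477 on the CD8aaT arrays against 2061 to 2961 on the CD8abT arrays. Blk, a kinase of B cells, had intensities of 16.7, 593 and 130 on the CD8aaT arrays and 19.9, 27.1 and 21 on the CD8abT arrays, and its difference of 2.28 ± 0.83 was not called. Among interferon-induced genes the median CD8aaT minus CD8abT difference was 0.34, 0.92 and 0.72 in replicates 1, 2 and 3, with 13, 13 and 12 of 14 genes higher. In the average over the pairs, the kinase genes Sgk1 (-1.06 ± 0.12) and Dgka (-1.05 ± 0.18) were lower, with -1.74, -0.21 and -1.24 for Sgk1 and -1.53, -0.56 and -1.06 for Dgka in the NKT, CD8 and B cell pairs.

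Splits of the 6 arrays of a T cell pair into 3 and 3 number 10, too few for a share under 0.05. In the NKT pair 1 of 10, the real one, called 202 probe sets, and the highest of the others called 0. In the CD8 pair 1 of 10 called 23, and the highest of the others, CD8abT replicate 1 with CD8aaT replicates 1 and 3, called 20. The real split parts all 3 replicate pairs, and the others that do so called 0 in both pairs, also with the replicate block, where the real ones called 601 and 398. For gene lists, 1 of 10 splits called 12 in the NKT pair with 0 as the highest other, and 1 of 10 called 5 in the CD8 pair with 3 as the highest other.

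For the average difference 1 of 100 splits within the pairs, the real one, called 200 probe sets and the highest of the others 129. Of 100 splits that part every replicate pair of the T cells, with the B cell arrays split freely, 1 called as many. The highest of the others, the real split with the whole B cell pair turned, called 159. That split keeps every group together, so it does not measure chance. Many of these splits keep whole pairs as they are, and the count can be carried by such a pair. The share therefore does not exclude chance for a difference common to the 3 pairs. For the 14 probe sets shared by all 3 pairs with the replicate block, 1 of the 4 orientations of whole pairs, the real one, called as many and the highest of the others, with the CD8 pair turned, called 4, too few orientations for a share under 0.05. Swaps that turn a pair only in part called 0 and do not bear on sharing, since such a pair keeps hardly any call.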
